A study of Mus musculus with 5 samples.

How the data were processed

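Forelimbs of mouse embryos on a mixed C57BL/6 and Swiss Webster background were studied at E11.5 (47 to 48 somites), with 3 control and 2 Prmt5cKO samples, grouped by the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and made into Illumina libraries. The submitters' processing notes name TopHat2 2.0.10, Bowtie2 2.1.0, Cufflinks 2.1.1 and the genome build mm10, without their roles or settings; the gene annotation is not given in the sources used here.

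The full table holds 28092 rows. Per the file headers, the authors gave 1 FPKM value per genotype, their log2 fold change of Prmt5cKO over control and a q-value, that is an adjusted p-value, for each row. How the replicates were combined, the test and the adjustment method are not given in the sources used here. The deposited log2 fold changes were checked against the FPKM columns and differed from the log2 of their ratio by at most 1.3e-05 over 20663 rows. A fold listed as 0 with a q of 1 was read as not tested. This held for 1374 rows above 0 FPKM, and 4353 further rows were at 0 in both genotypes. Only 15941 rows had a q below 1, so other rows joined a q of 1 to a fold other than 0. Whether the authors tested those is unknown, and they are not counted as untested here. Of all rows 4367 (15.5%) name no gene and hold 1.94% of the summed FPKM in control and 2.08% in Prmt5cKO; they were left out. Rows that name several genes number 597, and 499 rows repeat a symbol. A second, shorter deposited table of 208 rows has the same columns.

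The files used here hold no values per sample. The limma fit on log2(FPKM + 1) planned before the data were examined, its camera and fry gene list tests, the correlation between samples and each omission of a replicate could therefore not be run, and no p-value and no SD or standard error over replicates was computed here. Every q-value in the text is the authors' own. Whether it measures the spread between replicates is unknown, because the authors' test is not given in the sources used here. Depth per sample is unknown: among 909 rows with a mean under 0.05 FPKM no common step was visible (19 shared the commonest ratio), so reads could not be recovered. FPKM corrects for gene length and total, not for composition, so a few strong changes can shift all other ratios between the genotypes.

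A row was counted as changed where it named a gene, had a mean of at least 1 FPKM over the genotypes and an authors' q under 0.05, with the direction of the authors' log2 fold change. The comparison held 12332 rows that named a gene and reached this mean, whether or not they passed or were tested. For the gene lists, log2 ratios were computed as log2((Prmt5cKO FPKM + 1) / (control FPKM + 1)), with 1 row (the highest mean) per single symbol, 11660 genes in all; the pseudocount understates changes of low genes. The 30 lists were fixed before the data were examined: p53 targets, apoptosis, cartilage, limb patterning, Hox, hedgehog, BMP, FGF, WNT, S phase, G2 and mitosis, arginine methyltransferases, snRNP and splicing, ATF4, interferon, DNA repair, ribosome biogenesis, imprinted, immediate early, histone, mitochondrial, sex-linked and hindlimb or trunk genes, and markers of muscle, endothelium, red cells, macrophages, surface ectoderm, apical ridge and nerve. None of the 15 mitochondrial genes was measured, and that list is not analysed here. Each list median was placed among those of 10000 random lists of the same size, drawn gene by gene from 20 bins of mean expression with a fixed seed; lists of fewer than 5 measured genes were left out. On simulated data (11660 genes, 200 lists of 25) this marked 7.0% of lists with no shift, 42.0% at a log2 shift of 0.1, 95.5% at 0.2 and 100% at 0.4 as outside the middle 95%. The simulation shuffled ratios between genes of like expression, so list members did not vary together in it, as they can in real lists. Members in rows of several genes, and those listed at 0 in 1 genotype without a test, stayed out of the medians.

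Genes named in the text follow a rule set beforehand: Prmt5; the 10 largest rises and 10 largest falls past the threshold, leaving out predicted, ribosomal, microRNA, small nucleolar and similar symbols; the 3 members of each list with the smallest p, here the authors' q with ties set by the size of the change; and Sox9, Bmp4, Shh, Fgf10, Fgf8, Grem1, Trp53, Cdkn1a and Mdm2. The rule's demand that samples of the groups do not overlap could not be applied. Members outside it, such as those of counts of 5 or fewer and untested genes, were chosen after their values were seen.

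Coordinates are from GENCODE M21 on GRCm38 (mm10), the build in the processing notes, and for Erdr1 from RefSeq GRCm38.p6; GC content and length came from its longest transcript per gene, matched for 95.5% of the genes. Alternatives set beforehand and run were pseudocounts of 0.1 and 0.01, no minimum level, a minimum of 5 FPKM, rescaling by the median ratio, quantile normalization, a q under 0.1 and a 2-fold limit. Added after seeing the data were the omission of X- and Y-linked genes, of untested rows, the inclusion of unnamed rows or of rows of several genes, and 1 row per symbol. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.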

Results

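RNA was sequenced from forelimbs of mouse embryos at E11.5, with 47 to 48 somites, when the limb bud grows out under an ectodermal ridge and the first cartilage condensations form. The samples were 3 controls and 2 Prmt5cKO, described as biological replicates. In Prmt5cKO embryos both floxed copies of Prmt5 met Prx1Cre, a recombinase active in the mesenchyme of the limb bud. Prmt5 encodes an arginine methyltransferase whose substrates include histones and the Sm proteins of the splicing machinery. The comparison asks which transcripts differ when the mesenchyme loses this enzyme. The values used here are 1 FPKM (fragment counts scaled to transcript length and library total) per gene and genotype, computed by the authors over the replicates, so no value below carries an SD, and the depth of each sample is unknown.

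In Prmt5cKO forelimbs most known targets of p53, the transcription factor that answers DNA damage and other stress, were higher than in controls, and most genes of the cartilage programme were lower. Cdkn1a, a cell cycle inhibitor, went from 3.45 FPKM in control to 19.9 in Prmt5cKO, and Gdf5, a ligand of the BMP family made in the joint-forming mesenchyme, from 12.9 to 2.67, with log2 fold changes of 2.53 and -2.27 and q-values listed as 0 in the authors' deposited table. Signals of the limb bud were divided, with 4 rises and 8 falls among 31 BMP genes. Bmp4 went from 16.1 to 32.4 FPKM, Grem1, a secreted BMP antagonist, from 8.0 to 23.5, and Fgf8, the growth factor of the apical ectodermal ridge, from 7.17 to 14.4, with log2 fold changes of 1.01, 1.56 and 1.0 in the authors' deposited table. Markers of macrophages were also higher, with 12 of 23 risen. The genotypes also differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, stood at 87.3 FPKM in control and 0.392 in Prmt5cKO, and the Y-linked Ddx3y at 0.0840 and 21.8. Every difference given here is therefore between values that also differ in these transcripts. For every difference other than these transcripts and the fall of Prmt5, deleted by design, genotype and embryo sex cannot be told apart as the origin.

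Prmt5 itself fell from 40.9 to 12.5 FPKM, 30.6% of the control value, with a log2 fold change of -1.71 and a q listed as 0 in the authors' deposited table. The gene lies on chromosome 14 from 54507187 to 54517525, on the minus strand, in GRCm38 (mm10) with GENCODE M21. Its FPKM covers the whole gene, so exons outside the deleted part count too. Which exons the conditional allele removes is not given in the sources used here. The tissue was the whole forelimb and Prx1Cre acts in the mesenchyme, so other cells can also contribute Prmt5 transcripts. The 30.6% is therefore no measure of how completely the gene was deleted.

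**Figure D1:**
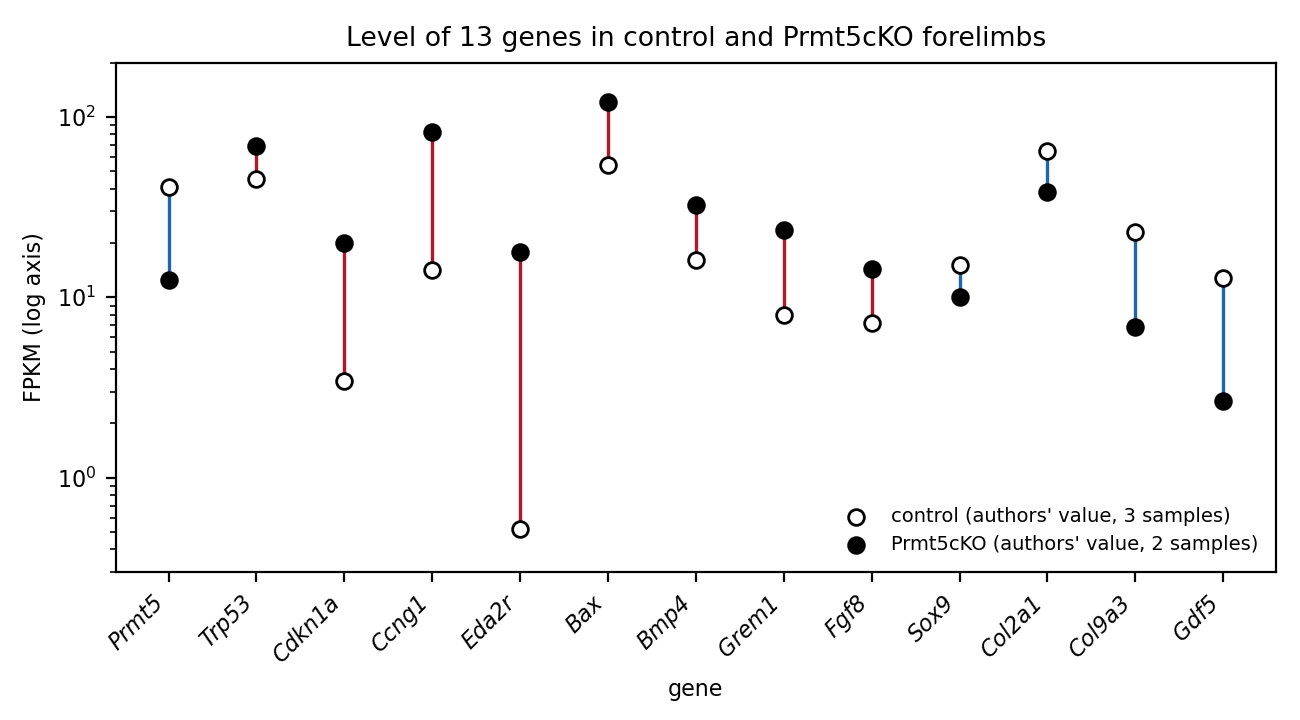
FPKM (log axis) of 13 genes, with 1 value per genotype as the authors gave it: open points are control, filled points Prmt5cKO, and the line joining them is red where Prmt5cKO is higher and blue where it is lower. Cdkn1a goes from 3.45 to 19.9 FPKM and Gdf5 from 12.9 to 2.67.

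Of 12332 rows that name a gene and reach a mean of 1 FPKM, 2709 (22%) changed at the authors' q under 0.05. Of these 548 rose and 2161 fell, so falls made up 79.8% of the changes; 1139 rows were not tested by the authors. At 2-fold or more, 68 rose and 164 fell. Among 10733 autosomal genes with coordinates, 4.38% rose and 17.6% fell at the authors' q under 0.05, whatever the fold. List counts of falls near that share do not set a list apart. The whole table leaned downwards: the median log2 ratio over 11660 single genes was -0.12 with a pseudocount of 1 FPKM, and -0.13 over the named rows without one. Among named rows at least 1.5-fold from a ratio of 1, 957 lay below and 229 above (80.7% below). After centring on the median ratio the same limit left 571 below and 373 above (60.5% below). Medians of gene lists are therefore given relative to the median of all genes, with their percentile among 10000 random lists of matched expression, which describes these 2 sets of values and is not a replicate test.

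Of 40 measured p53 targets 27 rose, 1 fell, 11 did not pass the threshold and 1 was not tested. The list median lay 0.78 above that of all genes on the log2 scale, above every random list. The X-linked receptor gene Eda2r rose from 0.520 to 17.9 FPKM, and Ccng1, a cyclin, from 14.2 to 82.2. Their log2 fold changes were 5.11 and 2.53 in the authors' deposited table. Trp53, which encodes p53, rose from 45.5 to 68.6 FPKM (log2 fold change 0.59, q = 9e-08), and Mdm2, its ubiquitin ligase, from 16.7 to 21.6 (0.37, q = 2.4e-05) in the authors' deposited table. Sesn1, a stress-induced inhibitor of growth signalling, was the member that fell, with a log2 fold change of -0.52 in the authors' deposited table. Among the 10 largest rises by the naming rule were also Ptprv, a receptor tyrosine phosphatase (0.315 to 3.93 FPKM), the non-coding RNA Pvt1 (0.211 to 2.02 in 1 of its 2 rows) and Ano3, a membrane protein of the anoctamin family (0.0772 to 6.15).

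Genes of the apoptosis machinery moved in part. Of 29 measured, 5 rose, 2 fell, 18 did not pass and 4 were not tested, and all 5 that rose are also p53 targets: Bax, Bbc3, Fas, Pmaip1 and Tnfrsf10b. The pore-forming Bax rose from 54.2 to 121 FPKM and the death receptor Tnfrsf10b from 3.83 to 9.94, while Bmf, a cell death activator of the BH3-only class, fell from 19.5 to 9.80, with log2 fold changes of 1.16, 1.37 and -0.99 in the authors' deposited table. Bad, another of that class, was the other fall. The list median lay 0.10 above that of all genes, at percentile 97.48, just inside the middle 95% of random lists and above it in 6 of 9 alternative settings.

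Cartilage genes fell as a group. Of 25 measured chondrogenic genes 15 fell, 1 rose, 7 did not pass and 2 were not tested, and the list median lay at -0.56 relative to all genes, below every random list, and at -0.31 with no minimum level, which brings in 10 genes with a mean under 1 FPKM. Col9a3 and Col9a2, chains of the cartilage collagen IX, fell from 23.0 to 6.86 FPKM and from 27.0 to 10.2, with log2 fold changes of -1.74 and -1.41 in the authors' deposited table. Sox9, the transcription factor that starts cartilage formation, fell from 15.1 to 9.98 FPKM, with a log2 fold change of -0.60 and q = 8.4e-04 in the authors' deposited table. Runx2, a regulator of later bone formation, was the gene that rose, from 0.938 to 1.37 FPKM (log2 fold change 0.55, q = 0.0485 in the authors' deposited table). Members chosen after their values were seen, Sox6 and Fgfr3, were not tested by the authors and stood at 10.6 and 10.2 FPKM in control and 5.49 and 5.76 in Prmt5cKO.

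**Figure D2:**
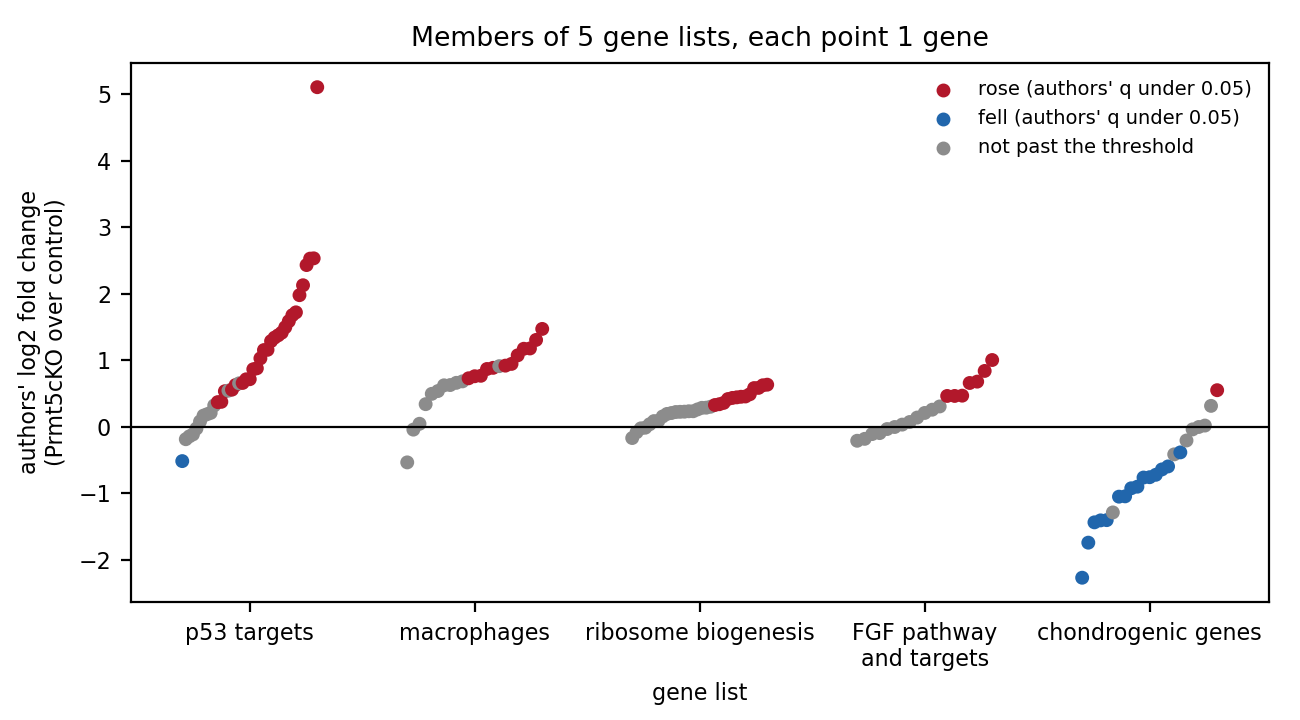
The authors' log2 fold change (Prmt5cKO over control) of each tested member of 5 gene lists, ordered within a list; each point is 1 gene with a mean of at least 1 FPKM, red where it rose and blue where it fell at the authors' q under 0.05, and grey otherwise. Of the p53 targets 27 rose and 1 fell, and of the chondrogenic genes 15 fell and 1 rose.

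Patterning factors of the limb mesenchyme went both ways. Of 45 measured, 7 rose, 9 fell, 21 did not pass and 8 were not tested, with a list median 0.05 above that of all genes (percentile 86.0). Osr2, a zinc finger factor of joints and connective tissue, fell by 1.19 on the log2 scale, while Tfap2c, an AP-2 factor, and the LIM homeobox gene Lhx2 rose by 1.06 and 0.46 in the authors' deposited table. Of 9 measured Hox genes with rows of their own, Hoxc6 rose by 0.91 on the log2 scale, Hoxd8 and Hoxd12 fell by 0.42 and 0.40 in the authors' deposited table, and 6 did not pass; their median lay 0.02 above that of all genes (percentile 50.6).

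In the FGF list 7 of 21 genes rose, none fell, 12 did not pass and 2 were not tested, and its median lay 0.25 above that of all genes, beyond every random list (0.12 with no minimum level, percentile 99.9). Besides Fgf8, the feedback inhibitor Spry1 and the transcription factor Etv4, both induced by FGF, rose by 0.68 and 0.46 on the log2 scale in the authors' deposited table. Fgf10, the mesenchymal ligand of limb outgrowth, was at 4.61 and 5.70 FPKM and did not pass (q = 0.201 in the authors' deposited table). BMP genes were divided: 4 of 31 rose (Bmp4, Grem1, Bmp5 and Acvr1), 8 fell, 18 did not pass and 1 was not tested, with a median at -0.06 relative to all genes (percentile 12.8). It lay at 0.08 (percentile 93.5) with a minimum mean of 5 FPKM. Among the falls were Gdf5 and the X-linked antagonist Chrdl1, which went from 12.8 to 5.88 FPKM. Of 18 hedgehog genes 3 rose, among them Grem1 and Gli1, 3 fell (Gli2, Hoxd12 and Osr1), 8 did not pass and 4 were not tested, with a median 0.02 above that of all genes (percentile 59.0). Shh, the ligand of the posterior limb bud, was below the minimum level at 0.172 FPKM in control and 0.860 in Prmt5cKO, with a log2 fold change of 2.32 and q = 6.6e-04 in the authors' deposited table. Of 27 WNT genes 1 rose (Rspo2), 5 fell, among them Wnt11, Rspo3 and Sfrp2, 19 did not pass and 2 were not tested. Log2 fold changes of those 3 were -0.91, -0.80 and -0.79 in the authors' deposited table, and the list median lay 0.03 above that of all genes (percentile 76.4).

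Of 34 measured genes for making ribosomes 13 rose, none fell, 19 did not pass and 2 were not tested, with a median 0.40 above that of all genes, beyond every random list. Noc2l, the X-linked pseudouridine synthase gene Dkc1 and Utp15, all needed to process ribosomal RNA, rose by 0.63, 0.45 and 0.44 on the log2 scale in the authors' deposited table. In the list of snRNP assembly and core splicing 3 of 33 rose (U2af1, Prpf8 and Snrpd3, the last an Sm protein that Prmt5 methylates), none fell, 27 did not pass and 3 were not tested. Its median lay 0.25 above that of all genes, again beyond every random list, and those 3 had log2 fold changes of 0.30, 0.37 and 0.48 in the authors' deposited table. In the arginine methyltransferase family with the partners of Prmt5, 11 measured, Prmt6 rose by 0.21 on the log2 scale, Prmt5 and Prmt10 fell by 1.71 and 0.41 in the authors' deposited table, and 8 did not pass. The median lay 0.17 above that of all genes (0.06 not set against them), at percentile 98.3, and within the middle 95% in 3 of 9 alternative settings.

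The cell cycle lists had few changed members. Of 35 S phase genes 2 rose (Hells and Cdt1), 3 fell (Tk1, Pold1 and Pole), 28 did not pass and 2 were not tested, and of 39 G2 and mitosis genes 4 rose, 5 fell, 20 did not pass and 10 were not tested. Gtse1 and Psrc1, both also p53 targets, rose by 1.34 and 0.88 on the log2 scale and the spindle gene Knstrn fell by 0.70 in the authors' deposited table. The medians of these lists lay 0.13 and 0.17 above that of all genes, at percentiles 98.9 and 99.9, although their changed members went both ways. Not set against all genes they were 0.02 and 0.05, so the lists lay above mainly because all genes leaned downwards. With no minimum level the relative medians were 0.08 and 0.11. Of 33 DNA repair genes none rose, 6 fell, 21 did not pass and 6 were not tested. Fancc, Atr and Brca2 fell by 0.55, 0.22 and 0.22 on the log2 scale in the authors' deposited table, and the median lay 0.03 above that of all genes (percentile 75.4).

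Of 20 genes of the ATF4 stress response 3 rose (Asns, Psat1 and Sesn2, the last also a p53 target), 2 fell (the cystine transporter gene Slc7a11 and the aminotransferase gene Gpt2) and 15 did not pass. The median lay 0.17 above that of all genes at percentile 99.9, and at percentile 96.7 when no minimum level was set. None of 7 measured interferon response genes passed (median -0.08 relative to all genes, percentile 27.7, and 0.04, percentile 76.9, with no minimum level). Of 22 imprinted growth genes 7 fell, none rose, 10 did not pass and 5 were not tested, with a median at -0.16 relative to all genes (percentile 0.14). The growth factor gene Igf2 fell from 234 to 161 FPKM, and Igf2, Rtl1 and Grb10 had log2 fold changes of -0.53, -0.91 and -0.45 in the authors' deposited table. Of 39 replication-dependent histone genes 2 rose (Hist1h2an and Hist1h2ao, though the other row of Hist1h2ao fell), 15 fell and 22 did not pass, with a median at -0.15 relative to all genes, below every random list. This leaves out 12 members listed at 0 FPKM in control and above 0 in Prmt5cKO, without a test; histone copies are nearly identical, so how reads were split between them is uncertain and the direction of the list is left open. Of 19 immediate early genes 3 fell (Cyr61, Jun and Gadd45b) and 16 did not pass (median 0.02 above all genes, percentile 65.8).

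**Figure D3:**
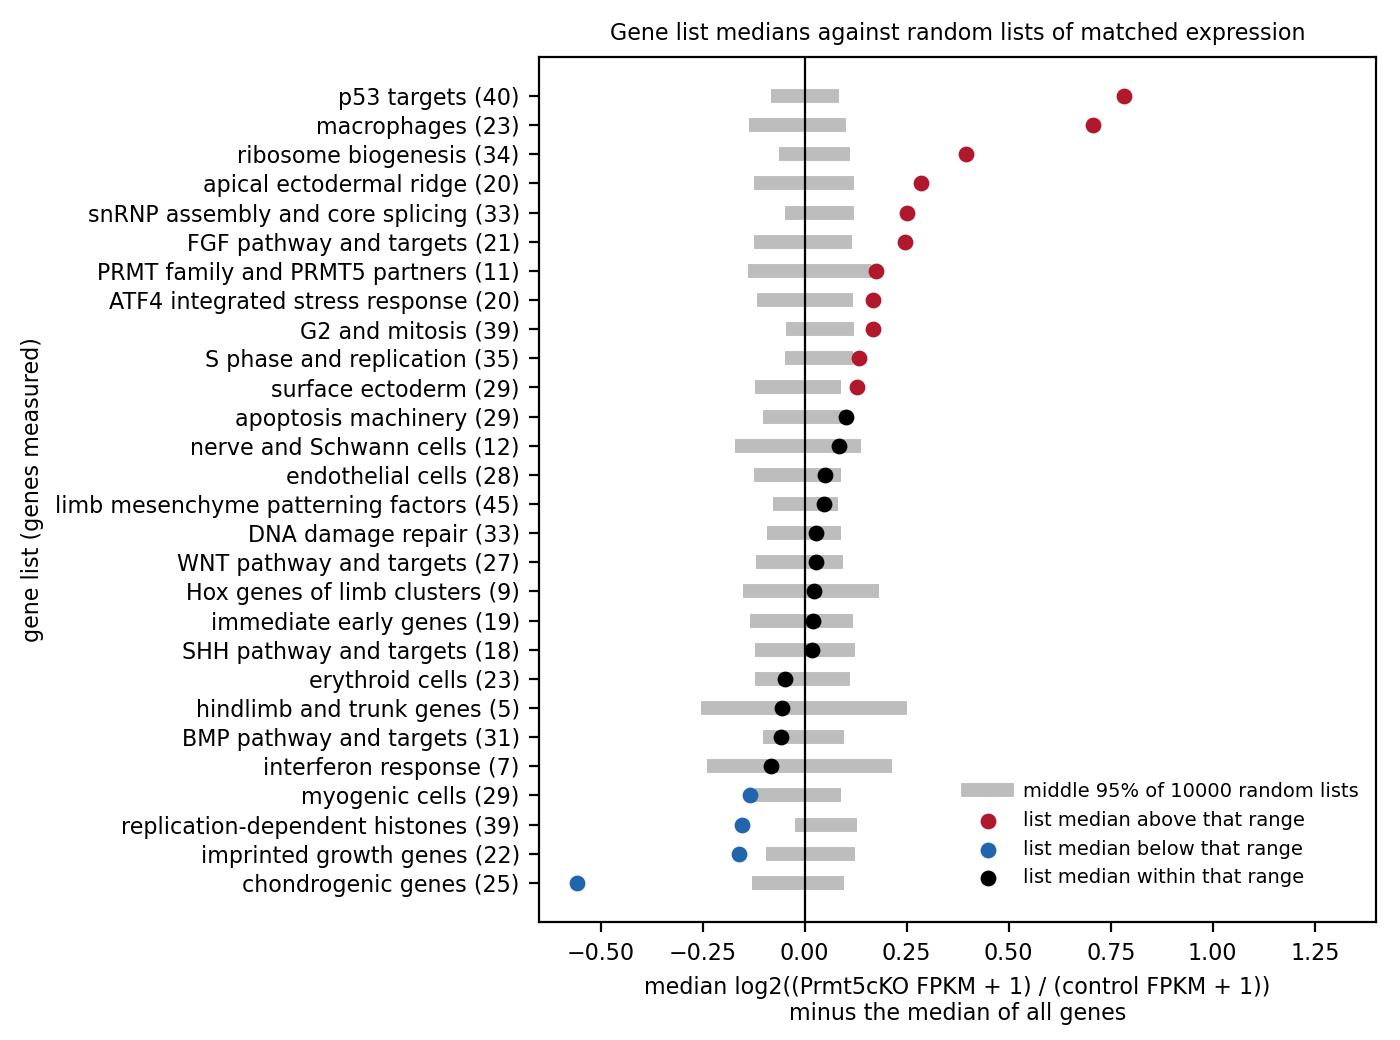
Median log2((Prmt5cKO FPKM + 1) / (control FPKM + 1)) of 28 gene lists, minus the median of all genes, as points; grey bars are the middle 95% of 10000 random lists of the same size and matched expression, and the number of measured genes stands in brackets. The p53 targets lie highest at 0.78 and the chondrogenic genes lowest at -0.56; the sex-linked list, at 3.78, is not drawn.

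Lists of marker genes for other cell types moved apart. Of 23 macrophage genes 12 rose, none fell and 11 did not pass, with a median 0.71 above that of all genes, beyond every random list. The receptor gene Csf1r rose from 3.36 to 5.57 FPKM, Emr1 (the F4/80 antigen) from 1.90 to 4.29 and the scavenger receptor gene Stab1 from 3.26 to 5.52, with log2 fold changes of 0.73, 1.18 and 0.76 in the authors' deposited table. Of 20 genes of the apical ectodermal ridge 6 rose, among them Fgf8, the transcription factor gene Sp6 and the phosphatase gene Dusp6; none fell, 12 did not pass and 2 were not tested. The ridge median lay 0.28 above that of all genes, beyond every random list, and Fgf8 and Dusp6 are also in the FGF list. The tissue was the whole forelimb, so the rise of Dusp6 (79.2 to 110 FPKM) cannot be placed in the ridge. Of 29 surface ectoderm genes 2 rose (Epcam and Tfap2a), the keratin gene Krt15 fell and 26 did not pass; the median lay 0.13 above that of all genes at percentile 99.7, but at percentile 89.8 with a minimum mean of 5 FPKM.

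Of 29 myogenic genes 6 fell, none rose, 21 did not pass and 2 were not tested. Mef2c, Tnnt1 and Myh3 fell by 0.25, 0.42 and 0.52 on the log2 scale in the authors' deposited table. The median lay at -0.13 relative to all genes (percentile 1.56). Without untested rows it was inside the middle 95% at percentile 3.0, and it lay at -0.29 (percentile 0.19) with a minimum mean of 5 FPKM. The endothelial list had 3 falls in 28 genes (Erg, Clec14a and Cd34), 23 not past the threshold and 2 untested, the erythroid list 3 in 23, among them Alas2 and Add2, with 19 and 1, and the nerve and Schwann cell list 2 in 12 (Erbb3 and Gfra3), with 9 and 1. Their medians relative to all genes were 0.05, -0.05 and 0.08, at percentiles 89.1, 20.6 and 88.8. Of 5 measured genes of hindlimb and trunk Meox2 fell by 0.53 on the log2 scale in the authors' deposited table and 4 did not pass (median -0.06 relative to all genes, percentile 31.0). With no minimum level that median was 0.08 (percentile 96.6). Of the 29 lists with at least 5 measured genes, 12 lay above and 4 below the middle 95% of random lists. About 1.45 would if the members of a list varied independently. Genes regulated together can leave that range more often, and some lists share members, so 1.45 is no chance expectation for these lists. Counts of 0 rest on the authors' q alone, as the tables used here hold adjusted values only.

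By the naming rule the 4 largest rises belonged to the Y-linked genes Kdm5d, Ddx3y, Uty and Eif2s3y, at 8.21, 8.02, 7.52 and 7.42 in the authors' deposited table. Together with Xist, which was not tested by the authors, these were the measured members of the sex-linked list, whose median lay 3.78 above that of all genes. X-linked genes known to escape X inactivation were lower in Prmt5cKO, with Kdm6a at 29.8 FPKM in control and 16.6 in Prmt5cKO, Kdm5c at 34.2 and 21.8, Eif2s3x at 174 and 121, and Ddx3x at 201 and 150; the authors did not test Kdm6a and Kdm5c. Without X- and Y-linked genes, 2601 rows changed, of which 533 rose and 2068 fell.

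The largest falls were in BC107364, from 1540 to 3.43 FPKM, and Rprl3, a copy of the RNA of RNase P, from 2301 to 9.88, with log2 fold changes of -8.81 and -7.86 in the authors' deposited table. By the naming rule, which leaves out predicted (Gm) and Rik symbols, next came the 2 rows of Erdr1 (-4.45 and -3.07), the kallikrein gene Klk1b22 (-4.29), BC006965 (-2.82) and the glutathione transferase gene Gstm6 (-2.47) in the authors' deposited table. Several of these have close paralogs that could share reads. Erdr1 has coordinates on the X chromosome in RefSeq GRCm38.p6, and whether it also lies on Y was not examined. Gdf5, the homeobox gene Irx1 (3.25 to 0.694 FPKM) and the carboxypeptidase gene Cpa4 (7.11 to 1.73 FPKM) completed the 10.

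A shorter table from the authors held 208 genes, 62 higher and 146 lower in Prmt5cKO. Its rows were exactly the 208 named rows of the authors' deposited table with q under 0.01, a change of at least 2-fold and a mean of at least 1 FPKM. It comes from the same samples and is not independent evidence.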

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

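Every test in this part was chosen after the result was seen, except that of scaling.

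Among the untested rows of the comparison, 14 histone rows were listed at 0 FPKM in control and above 0 in Prmt5cKO; the 13 that name a single gene held 10.8 to 2512 FPKM in Prmt5cKO. Histone mRNA is abundant in growing tissue, so a listed 0 can be a failed estimate, and no fold is given. Of 1068 rows without a gene name at 1 FPKM or more, which the comparison leaves out, 18 rose and 72 fell at the authors' q; 17 of the 72 were listed at 0 in Prmt5cKO and 1 of the 18 at 0 in control.

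The genotypes differed in sex-linked transcripts: Xist was 87.3 FPKM in control and 0.392 in Prmt5cKO, and the control value of 4 Y-linked genes was a median 0.465% of that in Prmt5cKO. If the embryos differed in sex, X-linked genes that escape X inactivation should be lower in Prmt5cKO, and 4 of 4 were, with a median log2 ratio of -0.57 against -0.15 for the other X-linked genes. Together these values argue against embryos of the same sex in both genotypes. They point to female control and male Prmt5cKO embryos, though no sex is given in the sources used here. For the 2354 autosomal genes past the threshold sex and genotype cannot be told apart, because neither value contains a visible share of the other sex. The fall of Prmt5, an autosomal gene deleted by design, is the change whose origin the genotype gives.

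Falls outnumbered rises 2161 to 548. GC content argues against itself as the cause, since the share of genes that fell differed by 2.02 percentage points between 5 equal classes of transcript GC. Gene length does not account for the whole excess: in the shortest of 5 equal classes of gene span there were 4.13 falls per rise, although the share of falls grew from 15.9% in that class to 28.9% in the longest. Scaling stays open, because the share lay so near the limit. After centring, 60.5% of named rows at least 1.5-fold from the centre lay below it, just past the limit of 60 set before this share was computed. By the limit alone scaling would not account for the excess. A Wilson 95% interval, added after the share was seen, ran from 57.3 to 63.6 and spans that limit. It treats rows as independent, though genes can vary together, and it does not measure the spread between replicates. An equal loss of all transcripts would cancel in FPKM, which is scaled to library total and holds no absolute amounts. These values can therefore neither show nor exclude such a loss.

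Macrophage markers were higher in Prmt5cKO, with a list median 0.71 above that of all genes. Blood carried into the dissection would bring red cell transcripts, but the erythroid median lay at -0.049 relative to all genes. A lower share of mesenchyme would raise all other cell types alike; the highest of 5 other cell type lists, surface ectoderm, lay at 0.13, and the apical ridge list, left out of that test, at 0.28. More macrophages, or more active ones, in Prmt5cKO limbs may account for it, but this was not tested beyond the list itself, and embryo sex stays open. None of the list's genes is in another list, 20 of them reached 1 FPKM in control, and its most abundant members did not pass: Coro1a (21 and 20.4 FPKM) and Pf4 (16.5 and 17.0).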

How the results depend on the processing

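No paired analysis was possible because the files used here hold 1 value per genotype. For the same reason the planned omissions of each replicate, variance settings, sample weights and camera with an estimated correlation were not run, and the depth that limits each value is unknown. The counts of changed genes stayed within 1.5 times the main count in all settings but the 2-fold limit (232 changed, 68 risen, 164 fallen), which by construction keeps fewer; falls were 70.7% there and between 79.5% and 80.0% in the others. Rescaling turned the sign of 3 calls and quantile normalization of 6; both keep the authors' q, so their counts could hardly move. Prmt5 stayed lower throughout (-1.51 to -1.71). The authors' shorter table would hold 264 genes with no minimum level and 89 with a minimum of 5 FPKM, where fewer genes qualify. Of 29 lists, 16 lay outside the middle 95% of random lists, and 14 to 17 of the 26 to 29 lists in the alternatives. Relative to all genes, 212 of 256 list medians moved by less than the random lists' SD, 44 by more, and 14 changed sign, all of lists inside the range. As log2 ratios not set against all genes, 2 lists outside the range changed sign. These were the ATF4 list with no minimum level (-0.0058) and surface ectoderm with a minimum of 5 FPKM (-0.043), from 0.05 and 0.01. On that scale several lists inside the range also changed sign, mostly with rescaling or quantile normalization. With rescaling by the median ratio, hedgehog genes went from -0.097 to 0.031 and WNT genes from -0.088 to 0.037. With no minimum level several relative medians shrank, S phase to 0.08 and G2 and mitosis to 0.11. Patterning factors reached percentile 98.9 without untested rows. The settings on X and Y, unnamed, untested and shared rows and single symbols were chosen after seeing the data.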

Other observations

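The gene groups and genes in this part were chosen after the data were seen. Among 164 groups of at least 8 genes that share a symbol root, 24 had a median outside the middle 95% of random lists. If the genes of a group varied independently, 8.2 would, but related genes can vary together. Collagen genes stood lowest: 16 of 33 fell and none rose, with a median log2 ratio of -0.49 against -0.12 for all genes. They included collagens that are not specific to cartilage, with Col3a1 going from 184 to 111 FPKM, Col1a1 from 13.7 to 8.83 and Col6a1 from 9.80 to 5.61. Of 15 Adamts genes, which encode proteases of the extracellular matrix, 8 fell and Adamts18 rose (median -0.45). Other matrix genes, such as Matn3, did not pass, and those that follow were picked for their falls, with no list fixed. Loxl1, a crosslinking enzyme of elastin, went from 7.14 to 1.93 FPKM, the heparan sulfatase gene Sulf1 from 63.9 to 25.2, Postn from 9.46 to 4.70, and the small proteoglycan genes Dcn and Kera from 7.45 to 3.17 and from 10.4 to 4.38. Of 14 Ift genes, needed to build cilia, 7 fell and none rose (median -0.30), with Ift43 going from 23.7 to 9.87 FPKM.

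In the other direction, 7 of 33 genes of the Ddx family of RNA helicases rose and 2 fell (median 0.11); the Y-linked Ddx3y is among the rises and the X-linked Ddx3x among the falls. Of 13 Prpf splicing factor genes 4 rose and 1 fell (median 0.19), with Prpf3 going from 19.7 to 35.0 FPKM in the larger of its rows. Mir34a, a microRNA gene that p53 activates, went from 0.217 to 4.44 FPKM, with a log2 fold change of 4.36 in the authors' deposited table. The macrophage genes Mpeg1 and C3ar1, outside the list, rose from 0.844 to 2.88 and from 0.722 to 1.90 FPKM. Mid1 fell from 7.68 to 2.27 FPKM. Rprl3 fell by 7.86 on the log2 scale in the authors' deposited table while Rpph1, the RNase P RNA gene it resembles, had a log2 fold change of -0.23 and q = 0.562.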
